A study of Oryza sativa with 8 samples.

How the data were processed

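RNA was measured by sequencing in leaves and roots of 2-week-old rice seedlings (Oryza sativa, cultivar Nipponbare) grown in liquid culture. Salt-treated plants received 150 mmol NaCl, the unit being given in the labels as an amount without a volume, and were collected after 24 hours together with untreated plants. The 8 libraries fall into 4 groups of 2 by their titles: leaf control, leaf salt, root control and root salt. The tissue field of the root libraries reads shoot, and that of the leaf libraries reads seedling, so the labels disagree. The titles and the description of the design name leaf and root, and the grouping follows the titles. Per the labels' protocols, each tissue was biologically replicated.

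The deposited values are FPKM, fragment counts scaled by transcript length and by the number of mapped fragments, given per gene and per library with a lower and an upper confidence bound. Per the submitters' processing notes, TopHat2 2.0.13, Cufflinks 2.2.1 and Cuffdiff (version not given) were used. Per the file headers, the values are in the gene tracking format of Cufflinks, and every gene carries the status OK. The genome build and the annotation are not given in the sources used here, and neither is the strandedness of the libraries. FPKM from genes that overlap or have near-identical copies therefore stay uncertain. Loci are on 12 chromosomes, and coordinates are printed 1-based, with 1 added to each deposited start. In 3 libraries (root control replicate 1, root salt replicate 1 and leaf salt replicate 2) the files list 185 further genes on unplaced sequence, all at 0, so 2 versions of the annotation were in use. These 3 libraries are spread over 3 of the 4 groups.

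Of the 55806 entries on chromosomes in each library, 9 belong to 4 identifiers that stand at several loci, and these were left out. The other 55797 genes have the same locus in all 8 libraries. Genes with at least 1 FPKM in 2 or more of the 8 libraries were tested, which left 23776. Values were transformed as log2(FPKM + 1), with no further scaling, and fold changes are on this scale, which understates the change of genes with low values. A model with 4 group means was fitted with limma 3.58.1 in R 4.3.3, with moderated variances that follow the mean level. Its contrasts were salt against control in leaf, salt against control in root, the difference between these changes (root minus leaf), and root against leaf in controls. A gene is called, or said to rise or fall, where the Benjamini-Hochberg adjusted p over the tested genes is under 0.05. All 4 groups share 1 estimate of the spread because each has 2 libraries. This design was fixed before the data were examined.

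Sequencing depth is not stated, but the confidence bounds carry part of it. With d the distance from the FPKM to its upper bound, the square of (2 × FPKM / d) gives an implied number of fragments. Within a tolerance of 0.02 it was a whole number for 39.2% to 42% of the genes with 1.5 to 200 implied fragments. Summed over genes it came to between 9060000 and 10700000 fragments per library. This is a lower estimate of depth if the bounds of the remaining genes are wider than counting error, which was not tested. Depth relative to leaf control replicate 1, from loci of at least 3000 bases with whole numbers in all 8 libraries, ranged from 0.927 to 1.10. For loci under 800 bases, implied fragments per FPKM were 1.15 to 1.23 times those of leaf control replicate 1 in the other libraries, relative to long loci. Values of short genes are therefore less comparable between libraries.

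No source used here pairs the gene identifiers with names. The deposited tables repeat the identifier in the name field, and 0 of the 55797 identifiers were found in the reference table of gene names, which belongs to the assembly ASM3414082v1. The 37 gene lists and 24 single genes chosen beforehand could not be matched to any gene, and their tests were not run. At most 2 identifiers that rose and 2 that fell are printed per contrast. They were taken by the largest log2 fold change among called genes whose 2 libraries in the higher group lay above both in the lower group, with a mean of at least 5 FPKM in the higher group. Genes at 0 in a library compared were passed over because no fold can be given, an exception made after values were seen: 3 for falling genes in leaf, and 5 and 10 for the difference between tissues, upwards and downwards. Groups defined from the data took the place of the lists, and were also chosen after the data were examined: genes preferring a tissue (called, and at least 2 on the log2 scale apart between root and leaf controls), the 100 genes with the highest mean FPKM in the controls of a tissue, and genes that neighbour each other on a chromosome. Tissue preference and abundance were also set on 1 control library and the salt change measured against the other, so that no library served both.

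Neighbouring genes were taken as consecutive tested genes whose loci do not overlap. Pairs called in the same direction, each gene at least 1 on the log2 scale changed, were compared with 100000 permutations of the calls within chromosomes, and the longest runs with 1000. Overlaps of calls were tested with Fisher's exact test, two-sided. Permutations used numpy 2.4.6 and pandas 2.3.3 in Python 3.11.15, and plots were drawn with matplotlib 3.10.9. The model was tested on simulated data with each gene's mean over all 8 libraries and its real spread, without a difference between tissues. The changed genes were drawn from those with a mean above 2 on the log2 scale. Far fewer genes were changed than were called in the data, so the rates below need not hold there. Of 100 genes changed by 1 on the log2 scale, 60% were recovered in leaf, 64% in root and 34% for the difference between tissues. Of 100 changed by 2, 82%, 90% and 80% were recovered. False calls among the unchanged of 23776 genes numbered 6, 8 and 5.

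Alternatives were other pseudocounts and filters, scaling to the 75th percentile, quantile normalization, no trend in the variance, only the groups compared, a size threshold, the replicate number as a block, and each library left out in turn. The annotation version as a covariate, removal of loci under 800 bases, and removal of 829 genes far more abundant in leaf than in root were added after the data were examined. With 2 libraries per group, no group is large enough for a test of outlying libraries or for counts over other splits of the samples.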

Results

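Transcript levels were measured by RNA sequencing in leaves and roots of 2-week-old rice seedlings, with and without 150 mmol NaCl for 24 hours, in 2 libraries per group. The series asks how salt-responsive genes differ between leaf and root. Each library had between 29122 and 30075 genes above 0 FPKM, and between 19726 and 21254 at 1 FPKM or more. The implied number of fragments lay between 9060000 and 10700000 per library. Spearman correlations over the 23776 tested genes were 0.969 to 0.983 between libraries of one group, 0.887 to 0.924 between treatments within a tissue, and 0.572 to 0.622 between tissues. The first principal component held 78.6% of the variance and separated root from leaf. The second held 11.2% and separated salt from control in both tissues, and the third, with 5.7%, placed salt on opposite sides of control in leaf and root. Replicates at least 2-fold apart on the log2(FPKM + 1) scale made up 1.63% of genes in leaf control, 1.33% in leaf salt, 3.89% in root control and 2.31% in root salt.

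Without salt, root and leaf differed in most of the transcriptome. Of the 23776 genes, 9299 were higher in root and 6722 were higher in leaf, and 751 and 1282 of them differed by at least 8-fold. The identifier LOC_Os09g24370 (chromosome 9, 14479023 to 14479844) had 2205 ± 358 FPKM in root and 0.510 ± 0.349 in leaf (SD, n = 2), a log2 difference of 10.52 ± 0.233 (SE, limma adjusted p = 2.51e-07). LOC_Os10g11500 (chromosome 10, 6370102 to 6370840) had 4718 ± 539 FPKM in root and 4.98 ± 0.562 in leaf (SD, n = 2), 9.62 apart on the log2 scale. On the leaf side, LOC_Os12g17600 (chromosome 12, 10080398 to 10081661) had 13380 ± 1370 FPKM in leaf and 62.9 ± 58.2 in root, and LOC_Os10g26940 (chromosome 10, 14171326 to 14172896) had 751 ± 9.51 and 2.92 ± 3.39 (SD, n = 2). Their log2 differences were -8.09 and -7.92. The contrast serves as the baseline for the groups of genes below: 1699 genes preferred root and 2332 preferred leaf, and the other 19745 are called shared.

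Transcripts abundant in leaf were present at different levels in the 2 root control libraries. Over 188 genes with at least 100 FPKM in leaf controls and a mean under 2% of that level in the 4 root libraries, the median level was 1.21% of leaf in root control replicate 1 (interquartile range 0.839% to 1.59%). It was 0.378% in root control replicate 2, and 0.265% and 0.374% in root salt replicates 1 and 2. In root control replicate 1 these genes were highest in 163 of 188 cases. The salt change in root of these 188 genes had a median of -0.62 on the log2 scale, and 47 of them were called lower. LOC_Os12g17600 and LOC_Os10g26940 are among the 188 genes.

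In leaves, salt changed 8027 genes, 33.8% of those tested. On the deposited scale 4504 were lower and 3523 higher, and 1463 and 1299 of them changed at least 2-fold. After scaling to the 75th percentile 4433 were lower and 3734 higher. After quantile normalization, which gives all libraries the same distribution, 3969 were lower and 3962 higher. The imbalance was thus kept under the former scaling and gone under the latter. Genes that prefer leaf fell most often, and the most abundant leaf transcripts lost part of their share. The identifier LOC_Os04g33920 (chromosome 4, 20543121 to 20544485) rose from 0.130 ± 0.0626 to 85.4 ± 31.4 FPKM (SD, n = 2), a log2 fold change of 6.21 ± 0.263 (SE, limma adjusted p = 4.11e-05). LOC_Os05g47730 (chromosome 5, 27345715 to 27346293) rose from 4.66 ± 0.00623 to 265 ± 91.9 FPKM, by 5.51 on the log2 scale (SE 0.225). LOC_Os03g22050 (chromosome 3, 12630705 to 12635182) fell from 117 ± 1.17 to 1.87 ± 0.025 FPKM, and LOC_Os10g40510 (chromosome 10, 21690274 to 21691088) fell from 115 ± 7.09 to 1.94 ± 0.206 FPKM (SD, n = 2). Their log2 fold changes were -5.36 and -5.30 (limma adjusted p = 2.22e-05 and 3.23e-05).

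Among the 2332 leaf-preferring genes, 822 fell in salt-treated leaves, 365 rose and 1145 were not called. The share that fell, 35.2%, compares with 17.4% of the 19745 shared genes (Fisher's exact test, two-sided, odds ratio 2.59, 95% interval 2.35 to 2.84, p = 3.99e-83, with genes taken as independent although they are not). The shares that rose were 15.7% and 14.7% (same exact test, odds ratio 1.07, p = 0.242). With leaf preference set on 1 control library and the change measured against the other, the median change of leaf-preferring genes was -0.26 in both arrangements, against -0.06 and -0.05 over all genes. Root-preferring genes in leaf rose in 248 cases and fell in 249 of 1699. Of the 100 most abundant genes in leaf controls, 26 fell, 2 rose and 72 were not called, and their share of summed FPKM was 29.4% and 30% in the control libraries and 26.6% and 25.7% with salt. Leaf preference was set anew at each pseudocount, so the genes in the group were not the same. With a pseudocount of 0.1 in place of 1, 23% of leaf-preferring genes fell and 12.5% rose, and with 5, 41.7% fell and 17.7% rose. Without leaf salt replicate 2, 17 of the 100 most abundant genes fell, and the number that rose was between 1 and 4 across libraries left out.

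The size of the leaf counts rests on all 4 leaf libraries. Without any 1 of leaf control replicate 1, leaf control replicate 2, leaf salt replicate 1 and leaf salt replicate 2, the genes that fell numbered 2899, 2856, 2820 and 2934, and without leaf salt replicate 2 the genes that rose numbered 2251.

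In roots, salt changed 10330 genes, 43.4% of those tested. On the deposited scale 6918 rose and 3412 fell, and 2352 and 1073 changed at least 2-fold. With only the groups compared in the model, 7577 genes were called in root and 7144 in leaf. Most of the excess of root calls over leaf calls thus depended on fitting all 4 groups with a shared spread. The most abundant root transcripts fell more often than they rose, and so did root-preferring genes, the latter by a margin that depended on the pseudocount. LOC_Os04g33920, which rose in leaf, also rose in root, from 1.34 ± 0.552 to 272 ± 24.3 FPKM (SD, n = 2), a log2 fold change of 6.88 ± 0.263 (SE, limma adjusted p = 4.85e-05). LOC_Os07g23660 (chromosome 7, 13366416 to 13367542) rose from 13.7 ± 1.03 to 1580 ± 767 FPKM in root (SD, n = 2), by 6.66 on the log2 scale (SE 0.31). LOC_Os07g42650 (chromosome 7, 25535919 to 25539300) fell from 109 ± 8.52 to 2.94 ± 0.0794 FPKM and LOC_Os01g40560 (chromosome 1, 22906443 to 22907811) from 133 ± 13.5 to 4.21 ± 0.388 FPKM (SD, n = 2). Their log2 fold changes were -4.80 and -4.68 (limma adjusted p = 4.49e-05 and 3.38e-05).

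The split of root calls depended on the scaling. The median change over all tested genes in root was 0.127 on the deposited scale, 0 after scaling to the 75th percentile and -0.03 after quantile normalization. The share of called genes that rose was 67.0%, 51.2% and 47.2% in the same order, with 3412, 4766 and 5262 genes lower. Without root salt replicate 1, 2257 genes fell.

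Of the 100 most abundant genes in root controls, 49 fell, 6 rose and 45 were not called, with a median change of -0.73. Their share of summed FPKM was 34.3% and 37.3% in root control libraries and 23.8% and 25.8% with salt. A single identifier, LOC_Os06g13680, chosen after its values were seen, held 9.94% and 12.7% of the sum in root controls and 5.78% and 6.33% with salt. Ranked on 1 control library and measured against the other, the 100 genes had medians of -0.80 and -0.67, while all genes had 0.122 and 0.133. Under scaling to the 75th percentile and quantile normalization, 57 and 40 of the 100 fell, and 5 and 11 rose.

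Among the 1699 root-preferring genes, 544 fell in salt-treated roots and 356 rose. The share that fell was 32.0%, against 13.1% of shared genes (Fisher's exact test, two-sided, odds ratio 3.14, 95% interval 2.80 to 3.50, p = 1.06e-81), and the share that rose was 21.0% against 30.3% (odds ratio 0.61, p = 7.58e-17). Under both scalings, with preference set anew on the scaled values, more root-preferring genes fell than rose. The shares were 37.8% and 38.4% lower and 15.8% and 15.9% higher. The shares of shared genes were not computed under these scalings. With preference set on 1 control library and the change measured against the other, medians were -0.005 and -0.101, below those of all genes, 0.122 and 0.133. In these arrangements 17.3% and 18.8% of root-preferring genes were at least 2-fold lower, and 16.5% and 12.5% at least 2-fold higher, so the excess of lower genes was small in the first. Root preference was also set anew at each pseudocount, so the genes in the group were not the same. With a pseudocount of 0.1 in place of 1, 18.2% of root-preferring genes fell and 17.2% rose, and with 5, 46.2% fell and 18.2% rose. Leaf-preferring genes in root rose in 579 cases and fell in 290 of 2332. Under quantile normalization, with preference set anew, 18.6% rose and 16.9% fell. With preference set on the other replicate, 5.6% were at least 2-fold lower and 13.2% higher against root control replicate 2. Against root control replicate 1, which held more leaf transcripts, 8.2% were at least 2-fold lower and 14.3% higher. The falls may thus rest in part on that library.

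**Figure D1:**
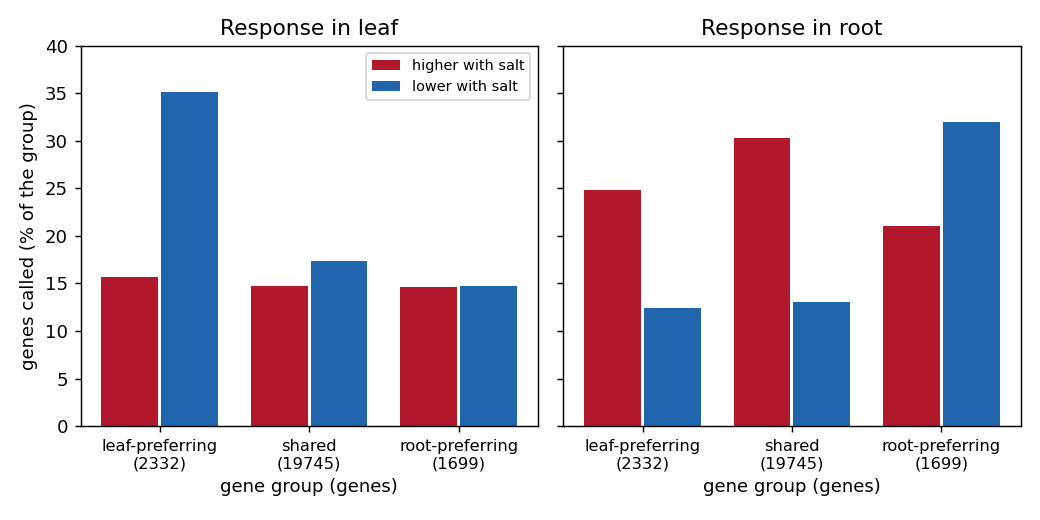
Bars give the percentage of genes in each group that were called higher (red) or lower (blue) with salt in leaf (left) and in root (right), with the number of genes under each group. In leaf, 35.2% of leaf-preferring genes were lower, and in root, 32.0% of root-preferring genes were lower.

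The leaf and root responses overlapped more than independent lists of the same sizes. Of the genes that rose, 1894 rose in both tissues, where 1025.1 would be shared by independent lists (Fisher's exact test, two-sided, odds ratio 3.52, 95% interval 3.27 to 3.80, p = 3.4e-245). Of those that fell, 1375 fell in both, against 646.4 (same exact test, odds ratio 3.72, p = 3.18e-221). Of the 4446 genes called in both tissues, 73.5% changed in the same direction. Leaf and root were compared with separate controls, but both contrasts use the same spread per gene, estimated from all 8 libraries. Genes with a small spread are more readily called in both tissues, which can raise the overlaps above those of independent lists. How much it did was not tested. Genes are also not independent replicates. Across genes, the log2 fold changes of leaf and root had a Pearson correlation of 0.331 and a Spearman correlation of 0.283.

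**Figure D2:**
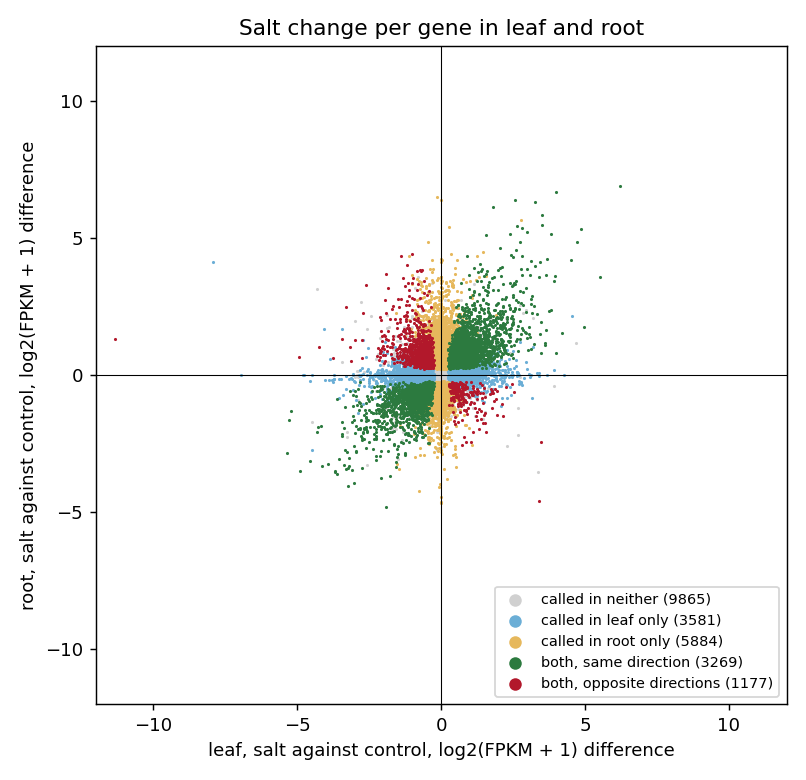
Each point is 1 of 23776 genes, with the salt change in leaf on the horizontal and in root on the vertical axis, both as differences of log2(FPKM + 1) between means of 2 libraries. Colours mark in which tissue a gene was called; the 4446 genes called in both lie mostly in the quadrants of equal sign (73.5%), and the leftmost point is a gene listed at 0 in both salt-treated leaf libraries.

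The salt response itself differed between root and leaf for 7805 genes, tested as the interaction of tissue and treatment. The change was more positive in root for 5496 of them and more positive in leaf for 2309. Among them, 955 genes were lower in leaf and higher in root, and 222 were higher in leaf and lower in root. With at least 2-fold changes in both tissues, 99 and 22 were left. These classes held fewer genes than independent lists would share, 1310.5 and 505.6 (Fisher's exact test, odds ratio 0.601 and 0.360). LOC_Os12g36880 (chromosome 12, 22599952 to 22601258) rose in root from 2.79 ± 0.745 to 340 ± 86.1 FPKM and had 47.9 ± 2.94 and 43.7 ± 1.27 FPKM in leaf (SD, n = 2), a difference of 6.61 ± 0.276 between the log2 changes (SE, limma adjusted p = 0.000111). LOC_Os08g09060 (chromosome 8, 5260152 to 5261299) fell in leaf and rose in root, with log2 changes of -3.30 and 2.48 and a difference of 5.77. LOC_Os01g08440 (chromosome 1, 4152864 to 4154680) rose from 8.33 ± 1.42 to 102 ± 6 FPKM in leaf and fell from 21.9 ± 0.504 to 3.63 ± 2.83 FPKM in root (SD, n = 2), a difference of -5.93. LOC_Os01g57968 (chromosome 1, 33531939 to 33533704) fell in root from 69.0 ± 40.9 to 5.27 ± 0.991 FPKM, with 250 ± 33.6 and 359 ± 61.2 FPKM in leaf, a difference of -3.87 (limma adjusted p = 0.00303).

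The direction of the interaction also depended on the scaling. The share more positive in root was 70.4% on the deposited scale, 55.0% after scaling to the 75th percentile and 48.4% after quantile normalization, with 3619 genes more positive in root and 3852 in leaf in the last case. Genes lower in leaf and higher in root numbered 543 after quantile normalization, and 543, 495, 499 and 566 without leaf control replicate 1, leaf control replicate 2, leaf salt replicate 1 and leaf salt replicate 2. Genes higher in leaf and lower in root numbered 371 and 403 under the 2 scalings, and 139, 147 and 129 without leaf control replicate 1, leaf salt replicate 1 and leaf salt replicate 2. Without leaf salt replicate 2, 1504 genes were more positive in leaf.

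Genes that changed at least 2-fold in the same direction lay next to each other on the chromosomes more often than permuted calls did. In root, 377 neighbouring pairs rose together, against 227.1 expected, and 130 fell together, against 48.3. In leaf, 131 pairs rose together against 69.5, and 207 fell together against 88.6. Over both directions the ratio of observed to expected pairs in root was 1.84, and it depended on the pseudocount, with 2.85 at a pseudocount of 5 in place of 1. Each count exceeded every one of 100000 permutations within chromosomes (permutation p = 1e-05, the smallest they can give). The longest run in root held 7 consecutive tested genes within 31.6 kb of chromosome 8 (5233768 to 5265389), which rose by 1.01 to 3.04 on the log2 scale. In leaf, 5 of these 7 genes fell, and the median change over the 7 was -1.66. Permuted calls gave no run of rising genes in root beyond 6.

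Other runs differed in how the tissues related. On chromosome 11 (15320188 to 15440045), 6 consecutive genes rose in root by 1.71 to 6.40, and 4 of them also rose in leaf, forming the leaf run at 15320188 to 15343857 with changes of 2.38 to 2.62. On chromosome 4 (5318060 to 5486773), 6 genes rose in root by 2.78 to 4.35, and 4 of them fell in leaf. Leaf levels of these 4 were low, with means of 0.922 to 2.90 FPKM in controls and 0.0746 to 0.557 with salt. These runs of 6 are no longer than permuted calls reached. The longest falling run in root held 6 genes on chromosome 7 (25045256 to 25098263), with changes of -1.76 to -1.16, beyond the 5 reached by permuted calls. In leaf, runs of 5 falling genes lay on chromosome 4 (17560646 to 17766782), chromosome 7 (21155350 to 21225911) and chromosome 9 (3456030 to 3496469), no longer than the 5 that permuted calls reached. A run of 11 genes on chromosome 7 (1319031 to 1438551) had a more positive change in root than in leaf, where 9 of the 11 fell, and permuted calls reached 8. The runs were picked for their length, and which of their genes are copies of each other was not examined.

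**Figure D3:**
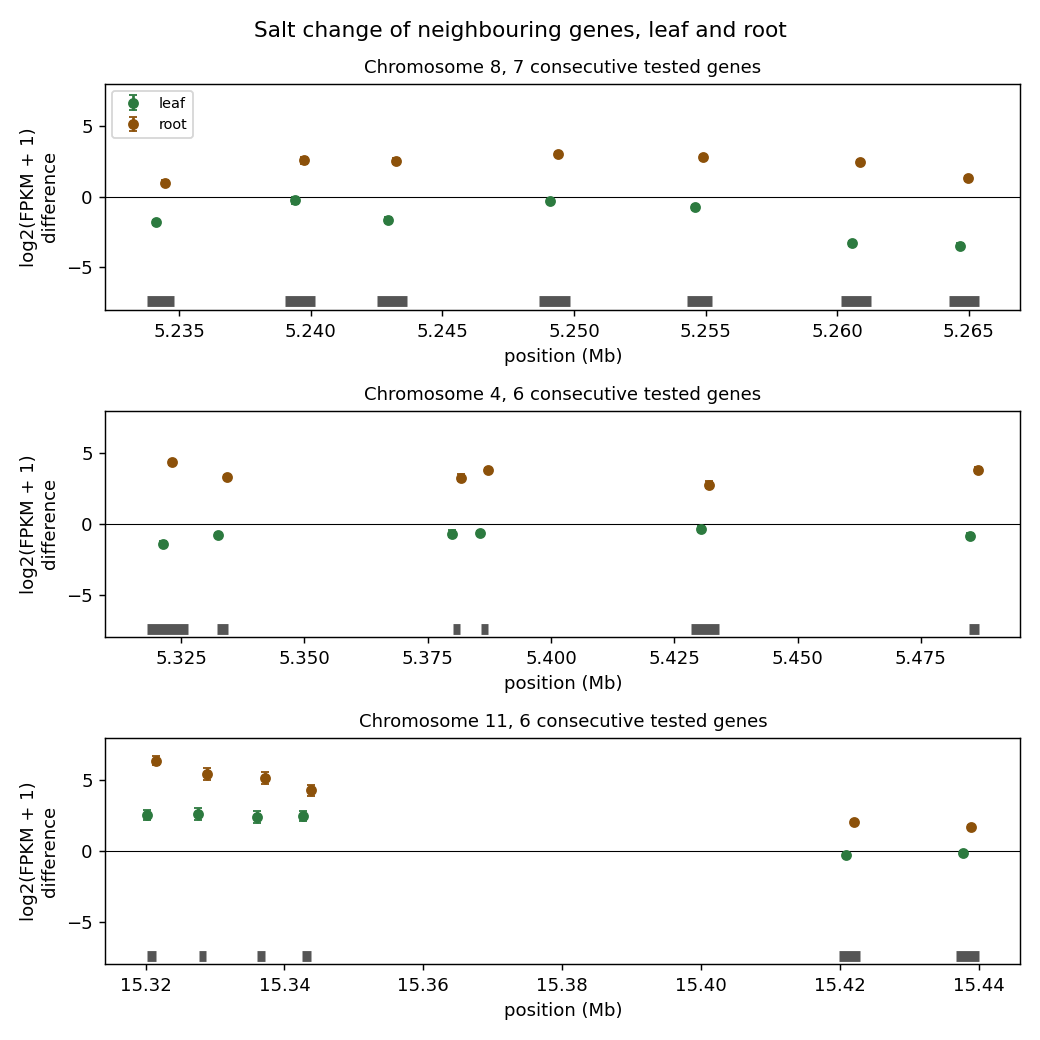
Salt changes of the genes in 3 runs that rose in root, on chromosomes 8, 4 and 11, plotted at their position in Mb. Points are differences of log2(FPKM + 1) in leaf (green) and root (brown) with their SE from limma, drawn side by side around the middle of each locus, and grey bars mark the extent of each locus. On chromosome 8 the root changes lie between 1.01 and 3.04, and 5 of the 7 genes fell in leaf.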

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

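The tests on leaf transcripts in root, on the library left out and on neighbouring genes were chosen after the results were seen. The rescaling without abundant genes was set before its result was seen. All results listed first differed between the tissues by the interaction of tissue and treatment in limma.

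The salt change differed between root and leaf for 7805 genes, and 955 of the called genes fell in leaf and rose in root, while 222 rose in leaf and fell in root. Of the printed identifiers, the change in root minus that in leaf was 6.61 for LOC_Os12g36880, 5.77 for LOC_Os08g09060, 3.64 for LOC_Os10g40510, 2.66 for LOC_Os07g23660 and 2.52 for LOC_Os03g22050 on the log2 scale. It was -5.93 for LOC_Os01g08440, -4.67 for LOC_Os01g40560, -3.87 for LOC_Os01g57968, -2.87 for LOC_Os07g42650, -1.93 for LOC_Os05g47730 and -1.49 for LOC_Os09g24370. LOC_Os05g47730 went from 0.241 to 13.9 FPKM in root and from 4.66 to 265 FPKM in leaf. Its difference came largely from the 1 added before the logarithm. In leaf, LOC_Os01g40560 had 0.0606 and 0.0515 FPKM without and with salt, and LOC_Os09g24370 had 0.510 and 0.671. At such levels a fall in leaf could hardly be seen, and the differences mostly give the root change. In runs of neighbouring genes the median difference was 3.55 on chromosome 8 from 5233768, 2.30 on chromosome 7 from 1319031, and 3.42 on chromosome 7 from 24466699. Permuted calls of the difference reached runs of 8. The runs of 7 genes from 5233768 and from 24466699 are no longer than that, while the run of 11 from 1319031 is. Genes in these runs were picked for differences of at least 1 on the log2 scale, so large medians were assured.

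Salt-treated roots had more genes higher than lower, 6918 against 3412. Root control replicate 1 alone did not account for this, since the share higher was 67.2% without that library. When each library was rescaled to its FPKM total without the 100 genes most abundant in root controls, the share was 51.4%, with 5099 genes higher and 4819 lower. Scaling to the 75th percentile, which singles out no abundant genes, gave 51.2%, and the median change over all genes was 0 in both cases. A fall of abundant transcripts that raises the FPKM of the others and a broad rise of the other genes would both give this, so they cannot be told apart on a relative scale without an external standard.

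Transcripts abundant in leaf were higher in root control replicate 1 than in the other root libraries. Its relative depth of 0.973 lay within the range of the other root libraries, 0.927 to 0.979, which argues against depth. Root salt replicate 1, made with the same annotation version, had a median of 0.265% of the leaf level, below both libraries of replicate 2, which argues against the annotation. Leaf material or leaf reads in that library may account for it and stay open: 86.7% of the 188 genes were highest there, but any cause that raises leaf-type transcripts together in that library would give the same. The set was redefined once, because a first version chosen without root control replicate 1 favoured that library, and no biological explanation was tested.

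Neighbouring genes were called together more often than permuted calls. Overlapping loci were left out of the pairs beforehand, so overlap was not tested. Among the 11624 pairs at least 5 kb apart the ratio of observed to expected pairs was 1.79 in root and 1.90 in leaf. This argues against touching gene models as the only cause. The expectation used call rates over all genes of a chromosome, and call rates of widely spaced genes were not accounted for. Reads shared between tandem copies stay open: replicate differences of the 790 pairs called together correlated at 0.105 in leaf control, 0.085 in leaf salt, 0.136 in root control and 0.362 in root salt. The mean, 0.172, lay between the bounds set for and against and rested largely on root salt, without which it was 0.109, while other neighbours had 0.026. Shared regulation of neighbouring genes may also give such pairs and was not tested.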

How the results depend on the processing

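Unless named here, the numbers of genes called per contrast, and per direction in the salt contrasts and their difference, stayed within 1.5 times their value under the alternatives run for each, 21 for root and 20 for the others. All 314 combinations of an alternative and a printed identifier, in the contrast it was picked for, kept direction and call in limma. The identifiers were picked for large changes there, so this was likely beforehand. Differences between tissues printed for identifiers picked in other contrasts were not rerun. Removal of short loci, of leaf-dominant genes, and the annotation covariate were chosen after the data were examined. After scaling to the 75th percentile the share of calls higher was 51.2% in root and 55.0% for the difference between tissues. After quantile normalization it was 47.2% and 48.4%, with 5262 genes lower in root, and 3619 and 3852 more positive in root and in leaf. Both scalings set the level of the libraries anew. With only the groups compared in the model, 558 genes fell in leaf and rose in root, and without a filter 17 of the 100 most abundant leaf genes fell; the cause was not tested.

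Requiring at least a 2-fold change left 2762 genes in leaf (1299 higher, 1463 lower), 3425 in root (2352 and 1073), 4106 for the difference (3046 and 1060), 8911 for root against leaf, and 837 changed the same way in both tissues, by construction. Genes lower in leaf and higher in root then numbered 99, and those higher in leaf and lower in root 22. With each library left out in turn, where the lone library is assumed to vary like the others, calls in leaf ranged from 5185 to 7975 (2251 to 3518 higher, 2820 to 4521 lower). Genes lower in root ranged from 2257 to 3190, and those more positive in leaf from 1504 to 2153. The lowest value of each range came without a library of the groups compared, and 4521, above the count with all libraries, came without root salt replicate 1.

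With the replicate number as a block, 7778 genes were called in leaf, 10012 in root, 7484 for the difference and 15962 for root against leaf, and 3113 changed the same way in both tissues. Deviations of libraries with the same number correlated between -0.021 and 0.07, except 0.213 for root salt with root control, and 2 pairs are too few to say that the number pairs the libraries. In root the number coincides with the annotation version, so the 2 cannot be told apart there. The mean SE of a log2 fold change was 0.414 at loci up to 800 bases and 0.132 over 5000, and how much of this comes from depth was not tested. Gene list alternatives were not run because no list could be matched.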

Other observations

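The test of the hypothesis below was chosen after the result was seen. A few genes were near absent in one condition and above 5 FPKM in the other, selected by level and not by a test. In leaf, 5 genes under 0.1 FPKM in both controls reached at least 5 FPKM with salt, with a median of 19.4 FPKM, and 16 went the other way, with a median control level of 15.5 FPKM. In root, 12 genes met the criterion in the direction of salt, with a median of 13.6 FPKM, and 7 in the direction of control. Loci under 800 bases made up 4 of the 5 and 13 of the 16 in leaf, and 7 of the 12 and 5 of the 7 in root, and most of these genes were listed at 0 rather than at a low value.

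Called genes were spread over all 12 chromosomes. In root, the share that rose was between 24.6% on chromosome 11 and 31.7% on chromosome 5, and the share that fell was between 12.6% on chromosome 3 and 17.7% on chromosome 10. In leaf, the share that fell was between 16.8% on chromosome 2 and 21.0% on chromosomes 9 and 11. These differences between chromosomes were not tested.

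Pairs of neighbours that changed together were also counted by distance, against the number expected from call rates over all genes of a chromosome. Call rates that differ between distance classes were not accounted for, so a ratio above 1 need not mean clustering within a class. For pairs under 1 kb apart the ratio was 2.44 for rising in leaf, 1.49 for falling in leaf, 1.42 for rising in root and 2.39 for falling in root. Among pairs 1 to 5 kb apart it was 2.34, 2.83, 1.80 and 3.23 in the same order. At 20 kb or more it was 0.96, 2.26, 1.70 and 2.12 in the same order. Over all pairs, salt changes of neighbours correlated at 0.130 in leaf and 0.142 in root, and replicate differences at 0.019 to 0.050.

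Because leaf-preferring genes in leaf and root-preferring genes in root fell more often than shared genes, a hypothesis is that salt may make leaf and root more alike. The SD over genes of the root minus leaf difference, taken over the 4 pairs of a root and a leaf library, lay between 1.703 and 1.753 on the log2 scale in controls and between 1.757 and 1.797 with salt. The gap between these ranges is smaller than the spread over pairs, and the pairs with root control replicate 1, which held more leaf transcripts, were the lowest. Genes at least 4-fold apart numbered 4135 to 4262 in controls and 4472 to 4577 with salt, a gap larger than the spread over pairs and opposite to the hypothesis. The gap closed under scaling to the 75th percentile (4168 to 4307 and 4294 to 4437) and quantile normalization (4179 to 4319 and 4288 to 4365). The 4 pairs of a treatment share 2 root and 2 leaf libraries, so they are not independent and their spread is a weak measure of noise. The count ran opposite to the hypothesis on the deposited scale only, and 2 libraries per group cannot decide the question.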
